A study of Mus musculus with 16 samples.

How the data were processed

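Genomic DNA from tails of 8 C57BL/6 mice was compared with DNA of 1 reference male mouse by array comparative genomic hybridisation, in which both DNAs, labelled with different dyes, compete for the same probes. Per the labels, each animal was hybridised on 2 arrays with the dyes exchanged, and the dye of each channel gave the direction of every ratio. The male parent, the female parent and 6 progeny were taken from the sample labels as separate animals, 1 value each, so that groups are 1, 1 and 6 animals.

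The deposited scanner files come from Agilent Feature Extraction 10.7.1.1, per the file headers, with 966371 spots and 6745 control spots per array. Their processed signals are intensities from which the software had subtracted background with a spatial trend and which it had dye-normalised with 1 linear factor per channel, per the file headers. The deposited log10 ratio of red over green equalled the ratio of these signals within 0.01 on the log2 scale for at least 99.99% of spots. Probe positions are those of mm9, per the file headers. The deposited series matrix holds log2 values, and per the file headers nothing more is said of how the authors made it. Set against the scanner files, its columns were the reference over the animal in both orientations (correlations of at least 0.99 in size), with medians between -0.0072 and 0.0181. Its direction was therefore turned, while the reason for its centring and its small departures from the scanner ratios stayed unknown.

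Control spots and spots with outlier flags (125 to 477 per array) were left out, and no spot was saturated. Spots of 1 probe were averaged, which gave 950749 probes. Log2 ratios were turned to animal over reference, each array was centred on its autosomal median, and both orientations were averaged. No loess or quantile normalisation was applied. The 2 orientations of an animal correlated between -0.46 and -0.11 over autosomal probes after turning, as a probe effect of the dyes would give. The mean removes such an effect only as far as it is equal on both arrays, which was not tested. Within the orientation with the animal in Cy5, arrays of different animals correlated between 0.354 and 0.495. In the other orientation, the array of progeny 6 correlated between -0.221 and 0.159 with the rest, so the mean of progeny 6 may keep part of such an effect.

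Regions were called in each animal by a recursive search for the interval with the largest sum of standardised log2 ratios over the square root of its number of probes. The threshold was 6, the longest interval 2000 probes and the shortest 3 probes. The mean and the median had to be at least 0.25 in size, with the same direction and a mean of at least 0.25 in each orientation. The same search was run on the difference between the orientations (divided by 2), and on 20 permutations of the probe positions within chromosomes. Tested on simulated regions, planted in the values of each animal at permuted positions over 950622 probes, the search found 26.2% of losses of -0.45 with 3 probes, 77.5% with 5 probes, 90% with 10 probes and 100% with 20 probes. For gains of 0.5 these shares were 50%, 85%, 96.2% and 100%. Losses of -0.9 were found at 92.5% with 3 probes and at 100% with 5 probes or more. Losses of -0.45 with at least 10 probes were found in progeny 6 at 80% and in every other animal at 96.7% or more.

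Calls of 1 direction that shared a probe were merged over animals. An animal carried a merged region when its mean was at least 0.25 in that direction in each orientation. The number of calls in 6 progeny and 2 parents was compared by an exact permutation test over 28 splits, and sharing by 1000 circular shifts. Windows of 10 probes were tested with limma, with Benjamini-Hochberg adjustment and a threshold of 0.05. In simulated windows (95054 windows, 200 changed) the test against the reference found 93% of changes of 0.25 and 100% of changes of 0.5. Scans fell on 4 days, the first with both parents and the other 3 with progeny only, so the day could not be separated from the parents. The reported fits have no term for the day, and an alternative for progeny against parents took it as a random block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0, SciPy 1.17.1, R 4.3.3, limma 3.58.1 and matplotlib 3.10.9 were used.

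The text names the 20 merged regions with the largest absolute mean in a carrying animal and the first 10 by that rank among regions of progeny and neither parent, a rule fixed before the data were examined together with the tests and most alternatives. Other regions and probes were named after their values were seen, as the text says. The files used here give probe positions and no gene names, and the gene table at hand uses another genome build, so no gene is named and the planned overlap with gene lists was not run.

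Alternatives covered the signal (normexp with an offset of 50 on median signals, since mean signals were not used here, or the series matrix), loess, dim probes, outlier flags, a running median over 1 Mb in place of a correction for base composition, the reference, the thresholds of the search, the orientations, merging, window size, the minimum in limma and leaving out each animal. Calls of at least 6 probes, leaving out progeny 6 in the counts of regions, and the scan day were added after the data were seen.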

Results

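The series asks whether DNA copy number differs from a reference in a family of C57BL/6 mice, a laboratory strain bred to be genetically uniform. It belongs to a study of low dose-rate gamma rays given to male mice before mating. The series title gives the exposure of the male parents as 0.05 mGy per day over 400 days. The opening of the series description instead calls the male of this family non-irradiated, so its exposure is not settled by the labels. No unirradiated family is among the samples, and no value below measures an effect of radiation.

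Tail DNA of 8 animals, 1 male parent, 1 female parent and 6 progeny, was hybridised against DNA of 1 reference male mouse of the same colony. Each animal was measured on 2 arrays, with the animal in Cy5 on one and in Cy3 on the other, which makes 16 arrays and 1 value per animal. The array holds 950622 autosomal probes with a median spacing of 2053 bases, 68 X probes and 23 Y probes. All values are log2 ratios of the animal over the reference, averaged over both dye orientations, and positions are mm9 coordinates. The spread of neighbouring log ratios lay between 0.187 and 0.284 on 15 arrays and was 0.456 on the array of progeny 6 with the animal in Cy3. Between 98.7% and 99.9% of the spots of an array were well above background in both channels. Errors given with regions are SE over probes of 1 animal, and probes are not biological replicates.

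The first comparison asks which autosomal regions differ from the reference in each animal. A block of 160.1 kb on chromosome 4 (101110482 to 101270535, 74 probes) was called as a gain in every one of the 8 animals, in progeny 6 without its last probe. A block of 18.75 kb on chromosome 1 (32581577 to 32600325, 13 probes) was called as a gain in the male parent and progeny 2, 3 and 4. Progeny 6 was called over the same block with 3 more probes on its left side. A further 77.72 kb on chromosome 12 (114893556 to 114971279, 13 probes) was called as a loss in progeny 5, and the longest call that a single progeny alone showed was 20 probes of chromosome 4 (78453216 to 78512630), a loss in progeny 5. Beyond these and a gain of 38 probes on chromosome 8 in the female parent, nearly all calls were short, with 198 of the 262 calls resting on 3 probes.

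The number of calls was 12 in the male parent, 44 in the female parent, and 56, 29, 14, 19, 78 and 10 in progeny 1 to 6. Calls of 3 to 9 probes were no more frequent than in arrays whose probe positions had been permuted within chromosomes. All calls together numbered 262 against 230 to 269 over 20 permutations, with 3 of the permutations at 262 or above. Calls of 10 or more probes numbered 16, against 0 to 1 over the same permutations. These 16 calls are not 16 separate places, since relatives were compared with the same reference. The chromosome 4 gain at 101110482 was called in 8 animals and the chromosome 1 gain at 32572660 in 5. The rest were the losses of progeny 5 on chromosome 12 and at 78453216 on chromosome 4, and the chromosome 8 gain of the female parent. The dye component, which is the difference between both orientations and holds no signal of animal against reference, gave 158 calls, of which 4 spanned 10 or more probes. At lengths of up to 9 probes the calls therefore could not be told from chance runs of probes, as a set. Outside the gains at 101110482 and 32572660, calls of 10 or more probes were no more numerous than the 4 of the dye component. The longest call of the dye component had 13 probes, in progeny 5, as many as the chromosome 12 loss of that animal.

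**Figure D1:**
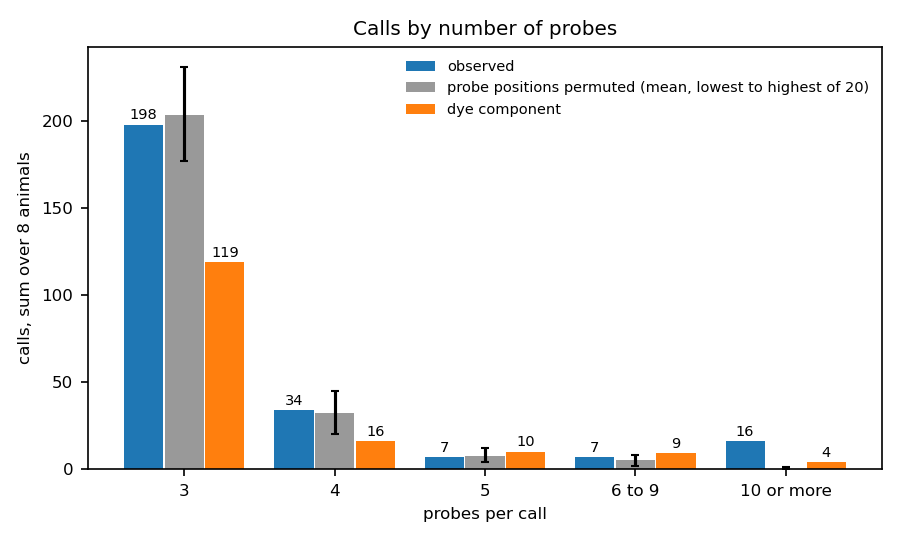
Number of calls summed over the 8 animals (vertical axis) by probes per call (horizontal axis), for the observed data, for permuted probe positions (bar at the mean of 20 permutations, line from the lowest to the highest) and for the dye component. Observed calls exceed the permuted range only at 10 or more probes, with 16 calls against at most 1. The 16 calls count the chromosome 4 gain at 101110482 in 8 animals and the chromosome 1 gain at 32572660 in 5 animals. The dye component gives 4 calls of 10 or more probes.

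The second comparison asks what the parents carried, what the progeny shared with them and what appeared in progeny alone. Calls merged into 247 regions, of which 1 was carried by all 8 animals, 25 by a parent and some progeny, 182 by progeny and neither parent, and 39 by a parent and no progeny. Regions with a call of at least 6 probes numbered 11, a limit chosen after the values were seen. Of these 11 regions, 1 was carried by all 8 animals, 3 by a parent and progeny, 5 by progeny and neither parent, and 2 by a parent alone. The last group holds the chromosome 8 gain, where progeny 5 and 6 read 0.24 and 0.18, under the minimum of 0.25.

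On chromosome 4 (101110482 to 101270535) the male parent had a mean log2 ratio of 0.93 ± 0.02 (SE, 74 probes) and the female parent 0.54 ± 0.02. Progeny 1 to 6 had 0.53, 0.52, 0.53, 0.52, 0.54 and 0.52, with SE between 0.01 and 0.03. Every animal passed the minimum of 0.25 in each dye orientation, from 0.90 and 0.95 in the male parent to 0.54 and 0.49 in progeny 6. The male parent lay 0.40 ± 0.02 above the mean of the other 7 animals. On the scale set by the X probes of the female parent, 3 copies against 2 correspond to 0.50 and 4 copies against 2 to 0.86. With normexp signals that scale gives 0.33 and 0.57, the male parent had 0.86 and the other 7 animals a mean of 0.49. With the median of the other 7 animals in place of the reference, the male parent kept 0.40, while the other 7 animals, each compared with carriers, lay between -0.05 and -0.02.

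**Figure D2:**
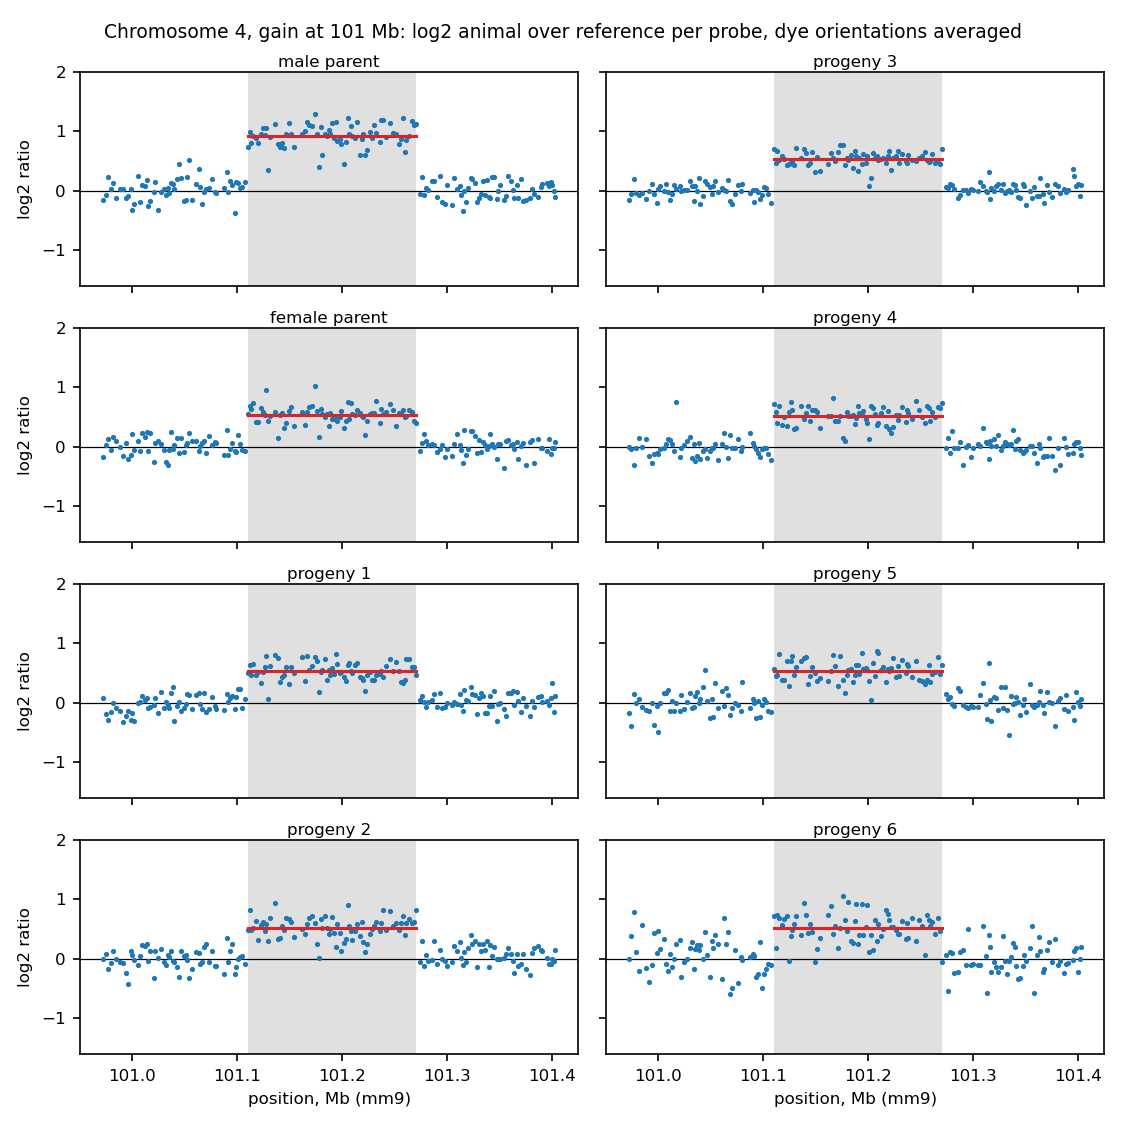
Log2 ratio of each probe (vertical axis) along chromosome 4 in Mb, mm9 (horizontal axis), 1 panel per animal, both dye orientations averaged. The shaded block is the region 101110482 to 101270535 and the red line its mean, 0.93 in the male parent and between 0.52 and 0.54 in the other 7 animals.

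On chromosome 1 (32572660 to 32600325, 16 probes after merging) the male parent had 0.51 ± 0.07, and progeny 2, 3, 4 and 6 had 0.46 ± 0.08, 0.45 ± 0.06, 0.45 ± 0.06 and 0.45 ± 0.09. The female parent lay at -0.02 ± 0.02, progeny 1 at 0.02 ± 0.04 and progeny 5 at 0.01 ± 0.05. Over the 13 probes from 32581577 the called values were 0.63 in the male parent and 0.57, 0.57 and 0.54 in progeny 2, 3 and 4. The region was thus carried by 4 of 6 progeny, 66.7% (95% exact Clopper-Pearson interval 22.3% to 95.7%). With the median of the other 7 animals as reference, carriers among them, the male parent had 0.20 and progeny 2, 3, 4 and 6 had 0.12, 0.13, 0.11 and 0.10. Apart from the chromosome 4 gain, no other region of at least 6 probes was carried by the male parent and by progeny. A gain of 7 probes on chromosome 15 (100175814 to 100195131) had 0.36 ± 0.11 in the male parent, and 0.25 ± 0.09 in progeny 2, where the orientation with the animal in Cy5 gave 0.06. With normexp signals the male parent had 0.12 there.

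**Figure D3:**
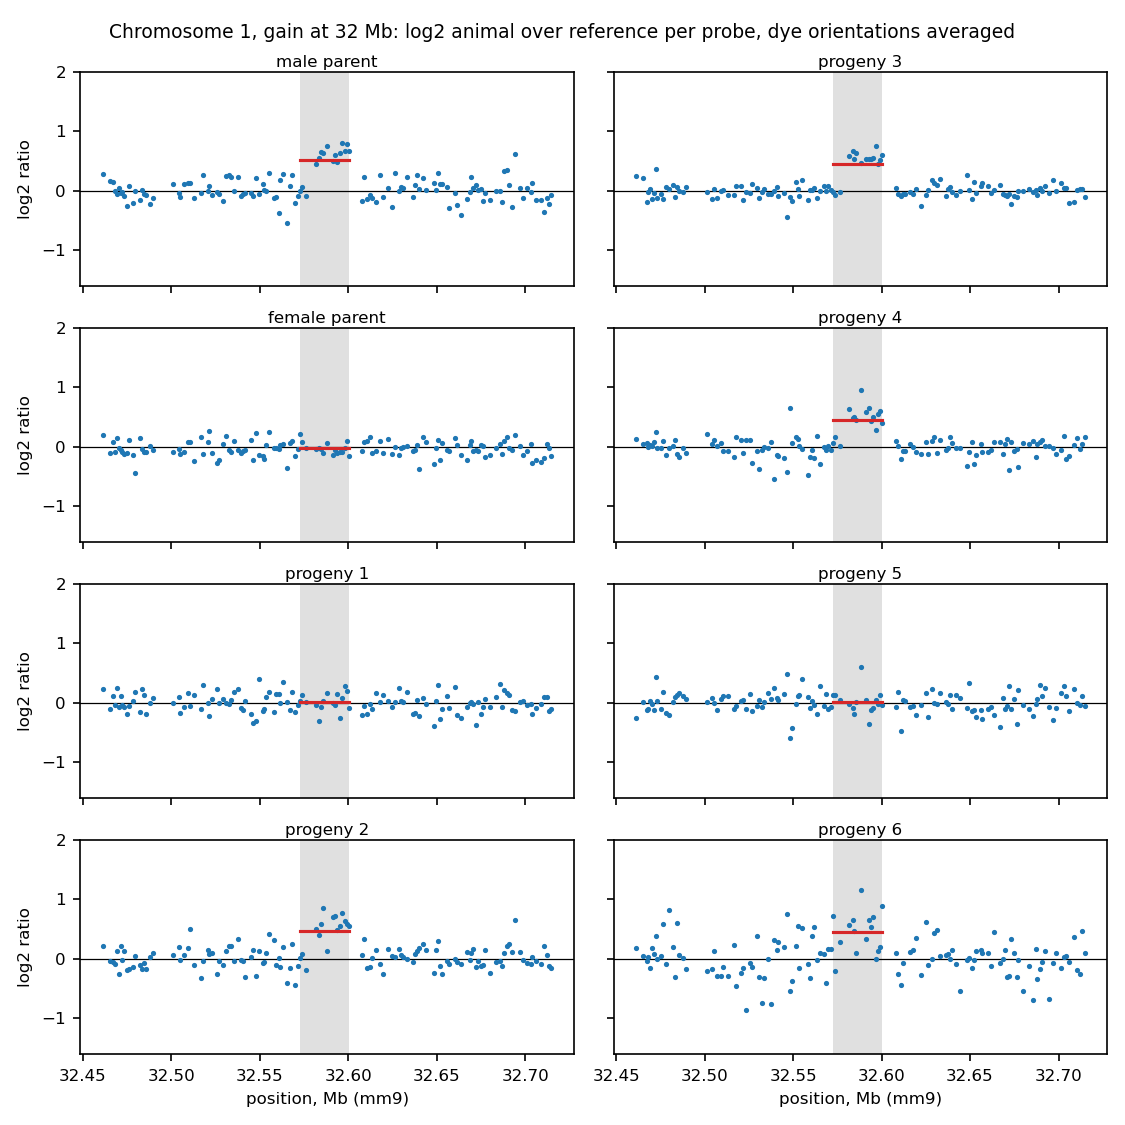
Log2 ratio of each probe (vertical axis) along chromosome 1 in Mb, mm9 (horizontal axis), 1 panel per animal, both dye orientations averaged. The shaded block is the merged region 32572660 to 32600325 and the red line its mean, between 0.45 and 0.51 in the male parent and progeny 2, 3, 4 and 6 and between -0.02 and 0.02 in the other 3 animals.

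On chromosome 12 (114893556 to 114971279, 13 probes) the female parent, called over its last 7 probes alone, had -0.46 ± 0.12 and progeny 5 had -0.52 ± 0.09. Progeny 6 lay at -0.11 ± 0.06, and the other 5 animals lay between -0.06 and 0.01. A gain of 38 probes on chromosome 8 (102132083 to 102242602) was called in the female parent at 0.29 ± 0.03. Progeny 5 and 6 had 0.24 ± 0.03 and 0.18 ± 0.05 there, under the minimum of 0.25, and the other 5 animals lay between -0.02 and 0.02. A loss of 7 probes on chromosome 5 (126312454 to 126329901) had -0.35 ± 0.08 in the female parent, -0.29 ± 0.08 in progeny 5 and -0.34 ± 0.16 in progeny 6.

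The largest loss, on chromosome 3 (25417435 to 25444229, 4 probes), was called in the female parent, progeny 5 and progeny 6 and in no other animal. Their means were -1.49 ± 0.25, -1.46 ± 0.27 and -1.57 ± 0.32, and all 4 probes were at -0.25 or below in each of them. The other 5 animals lay between -0.02 and 0.16. Altogether 11 regions, all of them losses, were carried by the female parent, progeny 5 and progeny 6 alone. In 10 of these 11 regions only 1 probe was at -0.25 or below in all 3 animals, and in 6 of the 11 the mean of the strongest carrier fell under 0.25 in size without its most extreme probe. On chromosome 6 the probe at 104241394 to 104241453 read -4.30, -4.40 and -3.88 in the female parent, progeny 5 and progeny 6, and between -0.16 and -0.02 in the other 5 animals. On chromosome 16 the probe at 40851536 to 40851595 read -3.25, -3.20 and -3.33 in the same 3 animals. On chromosome 7 the probe at 141019208 to 141019267 read -3.15, -2.87 and -3.21, while the other 3 probes of its region averaged -0.03 in the female parent. The probe readings were chosen after the values were seen.

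**Figure D4:**
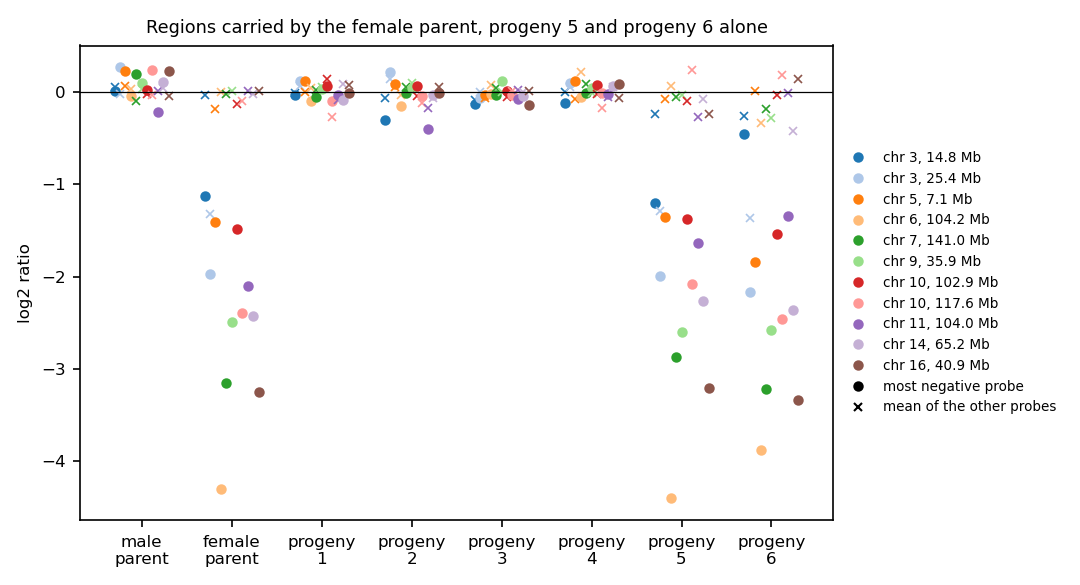
Log2 ratio (vertical axis) in each animal (horizontal axis) for the 11 regions carried by the female parent, progeny 5 and progeny 6 alone, with the probe that was most negative in the female parent as a dot and the mean of the region's other probes as a cross. The dots lie between -4.40 and -0.46 in these 3 animals and between -0.41 and 0.27 in the other 5, and only the region of chromosome 3 from 25417435 has its cross below -1 in them.

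Among the 20 regions with the largest absolute mean in a carrying animal, 15 were losses and 5 were gains, 17 held 3 probes, and the means ran from 0.81 to 1.57 in size. Besides chromosome 3 at 25417435, chromosome 6 at 104238274, chromosome 7 at 141017667, chromosome 16 at 40847733 and the chromosome 4 gain, regions of a parent were chromosome 14 (65227099 to 65230923), chromosome 3 (132549431 to 132553080) and chromosome 10 (117620044 to 117625750). Their values in the female parent were -0.82, -1.03 and -0.87. In 9 of the 20 regions a single probe was past 0.25 in every carrier. Regions of 3 probes with 1 carrier could not be among these 9, since the call rule asks for a median of at least 0.25. In 6 of the 20 the mean of the strongest carrier fell under 0.25 in size once its most extreme probe was left out.

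The other 12 of these 20 regions were carried by progeny and neither parent, and the first 10 of them by rank all held 3 probes. Progeny 1 had losses on chromosome 7 (111324029 to 111329703, -1.27 ± 0.81, also carried by progeny 2 at -0.69 and progeny 6 at -0.33), chromosome 17 (59372823 to 59377719, -0.96 ± 0.47) and chromosome 8 (6121345 to 6125281, -0.81 ± 0.41). Progeny 2 had losses on chromosome 11 (43824159 to 43828761, -1.08 ± 0.98), chromosome 6 (38034157 to 38038040, -0.89 ± 0.57) and chromosome 3 (65358001 to 65363606, -0.83 ± 0.58, also carried by progeny 4 at -0.45 and progeny 1 at -0.32). It also had a gain on chromosome 7 (80193255 to 80203583, 0.82 ± 0.58). Progeny 5 had gains on chromosome 15 (84373221 to 84378879, 0.87 ± 0.62), chromosome 1 (191312794 to 191316396, 0.87 ± 0.33, also carried by progeny 1 at 0.36) and chromosome 3 (89308592 to 89312969, 0.81 ± 0.46, also carried by progeny 6 at 0.36). It had a loss on chromosome 1 (23058242 to 23061861, -0.85 ± 0.26). Progeny 6 had a loss on chromosome 7 (126943608 to 126947479, -1.15 ± 0.41), where the female parent read -0.47 and progeny 5 read -0.54. The 2 arrays of an animal differed widely in many of these regions, with the larger part from 1 array. With the animal in Cy5 and in Cy3, progeny 1 had -2.23 and -0.32 at 111324029, -1.6 and -0.32 at 59372823, and -1.31 and -0.32 at 6121345. Progeny 2 had -1.89 and -0.29 at 43824159, -1.50 and -0.27 at 38034157, and 1.36 and 0.28 at 80193255, and progeny 5 had 0.35 and 1.40 at 84373221. With normexp signals the value of progeny 2 at 111324029 on chromosome 7 turned to 0.04, progeny 5 had -0.17 at 23058242 and 0.10 at 191312794 on chromosome 1, and progeny 1 had 0.08 at the latter.

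Regions of at least 6 probes carried by progeny and neither parent numbered 5, each in 1 animal. The longest was the loss on chromosome 4 (78453216 to 78512630, 20 probes) in progeny 5, at -0.38 ± 0.05, with -0.42 and -0.34 in the orientations with the animal in Cy5 and in Cy3. The parents lay at -0.12 ± 0.04 and -0.02 ± 0.03 there. Progeny 5 also had a gain of 6 probes on chromosome 6 (5216964 to 5227978, 0.41 ± 0.12) and a loss of 6 probes on chromosome 10 (32672470 to 32693265, -0.39 ± 0.14). Progeny 2 had losses on chromosome 2 (57306949 to 57323579, 6 probes, -0.40 ± 0.16) and chromosome 18 (28777402 to 28796220, 7 probes, -0.38 ± 0.13). Permuted positions gave calls of up to 12 probes in progeny 5 and 11 in progeny 2, so the loss of 20 probes alone was longer than any permuted call of its animal. With normexp signals progeny 5 had 0.03 on chromosome 6 from 5216964, and progeny 2 had -0.07 on chromosome 2 from 57306949 and -0.09 on chromosome 18 from 28777402.

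The third comparison asks whether progeny held more regions than parents and whether they shared them. The 6 progeny had 34.3 ± 27 calls (SD, n = 6) and the 2 parents a mean of 28. The difference of 6.33 did not stand out in an exact permutation test (two-sided p = 0.786 over 28 splits, where the smallest possible p is 0.036). Counting calls of at least 6 probes, chosen after the values were seen, the progeny had 2.67 ± 1.51 and the parents a mean of 3.5, and the difference of -0.83 turned its direction (exact permutation p = 0.571). Apart from the chromosome 4 gain, 4 regions were called both in a parent and in a progeny, namely those on chromosome 1 at 32572660, chromosome 3 at 25417435, chromosome 7 at 141017667 and chromosome 12 at 114893556. Circular shifts of the progeny's regions gave a mean of 0.037 and at most 2 such regions (one-sided permutation p = 0.001 over 1000 shifts, the smallest they can give). The shifts stand for chance placement alone and remove what all animals share through the probes and the reference, so this p does not measure inheritance. Moreover, the regions on chromosomes 3 and 7 are among the 11 losses carried by the female parent, progeny 5 and progeny 6 alone. The one on chromosome 7 had only 1 probe past the minimum in all carriers.

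Mean levels of the 6 progeny and the 2 parents were also compared, without calling, on 95054 windows of 10 autosomal probes. No window differed between progeny and parents (limma, 0 windows at an adjusted p under 0.05), and 3152 windows had an unadjusted p under 0.05. With the scan day as a random block the count was also 0. On the chromosome 4 gain, the progeny averaged 0.54 and the parents 0.74 in the window 101115312 to 101135883, a difference of -0.20 ± 0.13 (adjusted p = 1.00). The parents were unlike in that window, with 0.90 in the male parent and 0.58 in the female parent, while the progeny lay between 0.51 and 0.58. In simulated windows a difference of 0.5 was found at all 200 planted places, with 11 false windows, and a difference of 0.25 at 0 of 200. Differences between these sizes were not simulated. The simulated difference was planted in all 6 progeny. A change in 1 animal is diluted in the mean of its group and was not simulated, so the absence of windows does not speak for such changes.

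Windows at which the 8 animals together differed from the reference numbered 7, all of them higher and all inside the chromosome 4 gain between 101115312 and 101268843, and 11 windows had an unadjusted p under 0.05. Their means lay between 0.54 and 0.60 (limma with a minimum of 0.1, adjusted p = 0.0103 to 0.0110, all 8 animals higher). The spread of the reference mouse itself is not part of this test. The count fell to 0 without the female parent or without any one of progeny 1, 2, 4, 5 and 6, was 6 without progeny 3, and stayed at 7 without the male parent, whose value stood apart.

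The last comparison checks the labels on the sex chromosomes, where a female against the male reference has a known difference. The female parent had a median log2 ratio of 0.86 ± 0.03 (SE over 68 probes) on X and -1.51 ± 0.28 (23 probes) on Y. The male parent had -0.02 ± 0.03 on X and -0.06 ± 0.04 on Y. Progeny 5 and 6 had 0.87 ± 0.03 and 0.82 ± 0.03 on X and -1.53 ± 0.26 and -1.19 ± 0.32 on Y. With normexp signals the female parent, progeny 5 and progeny 6 had 0.57, 0.53 and 0.54 on X and -0.40, -0.33 and -0.42 on Y. Without dim probes their Y medians were -1.0, -0.65 and -0.98. Progeny 1 to 4 lay between -0.04 and 0.01 on X and between -0.03 and 0.03 on Y. The labels name no sex for the progeny. On both chromosomes progeny 5 and 6 read like the female parent, and progeny 1 to 4 like the male parent. Medians of whole autosomes lay between -0.01 and 0.01 in every animal, the lowest on chromosome 3 of progeny 6 and the highest on chromosome 10 of progeny 2.

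**Figure D5:**
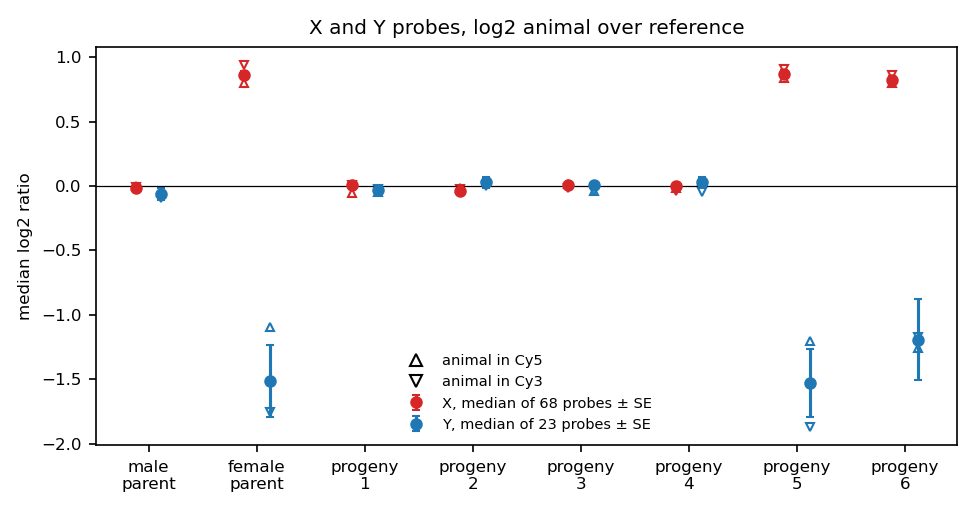
Median log2 ratio (vertical axis) of the X and Y probes in each animal (horizontal axis), filled dots for the mean of both orientations with SE over probes, open triangles for each orientation alone. The female parent, progeny 5 and progeny 6 lie between 0.82 and 0.87 on X and between -1.53 and -1.19 on Y, and the other 5 animals lie near 0 on both.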

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

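The tests of the loss on chromosome 4 in this part were chosen only after its values were seen. Each measure below was compared over the 6 progeny, and a value was picked out when its gap to the nearest other animal took up more than 0.625 of the whole range. Of 47 measures 13 were picked out, where chance alone picks about 1 in 20, and measures of the same array are not independent. The regions below entered because an animal was called there, so this rate does not hold for them.

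Progeny 6 had a spread of neighbouring log ratios of 0.456 on the array with the animal in Cy3, against at most 0.283 in the other progeny. It also stood apart, as the lowest, in the medians of 7 autosomes, namely chromosome 3 (-0.0102), 6 (-0.00522), 9 (-0.00473), 12 (-0.00907), 14 (-0.00933), 16 (-0.00406) and 18 (-0.00775), all of them far below the size of any called region. Progeny 3 had 451 outlier spots on the array with the animal in Cy5, against at most 223 in the other progeny.

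Progeny 2 stood apart on chromosome 2 (57306949 to 57323579) at -0.40 (-0.07 with normexp signals). Progeny 5 stood apart on chromosome 6 (5216964 to 5227978) at 0.41 (0.03 with normexp signals) and on chromosome 12 (114893556 to 114971279) at -0.52, where the female parent had -0.46.

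Progeny 5 stood apart on chromosome 4 (78453216 to 78512630) at -0.38 over 20 probes. Chance runs of independent probes are argued against, since the longest call over 20 permutations of its probe positions had 12 probes. Permutation removes any dependence between neighbouring probes, so noise shared by neighbours stays open. The dye component of progeny 5, which holds no signal of animal against reference, gave a call of 13 probes. The loss of 1 of 2 copies in all cells would lie at -0.86 on the scale of the X probes, and the mean lay 0.48 ± 0.05 above that (0.26 ± 0.05 with normexp signals and their scale). An equal dye effect on both arrays would cancel in the mean, but the call rule admits only regions past 0.25 in each orientation, so no reading here tests a dye effect (12 probes called with the animal in Cy3 alone read -0.44 ± 0.08 in Cy5). A loss in part of the cells may remain and was not tested, nor was any effect of the exposure, since no unirradiated family was analysed here.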

How the results depend on the processing

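Calls of at least 6 probes, leaving out progeny 6 in the counts of regions, and the scan day as a block were chosen after the data were seen, and all other alternatives before. The planned overlap with gene lists was not run. Unless the alternative itself shows the cause, as fewer probes or a looser threshold do, the cause was not tested.

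Calls over the 8 animals, 262 as reported, came to 116 with normexp signals, 124 without dim probes, 750 and 66 with score thresholds of 5 and 8, 1056 and 59 with at least 2 and 5 probes, 576 and 81 with minimum log2 ratios of 0.15 and 0.4, 565 without the orientation requirement, 935 with the animal in Cy5 alone, and 23 with at least 6 probes. In the same order the 247 merged regions became 100, 109, 723, 52, 969, 45, 548, 67, 545, 885 and 11. Regions of progeny and neither parent, 182 as reported, became 77, 74, 551, 35, 700, 29, 381, 55, 387, 453 and 5. The 25 regions of a parent and some progeny became 8 with normexp, 43 and 10 with the score thresholds, 95 and 9 with the probe minimums, 90 and 6 with the log2 minimums, 85 without the orientation requirement, 368 and 164 with Cy5 or Cy3 alone, and 3 with at least 6 probes. The 39 regions of a parent and no progeny became 14 with normexp, 14 without dim probes, 72 with the median of the other 7 animals as reference, 128 and 6, 171 and 6, and 76 and 5 with those 3 pairs of limits, 71 without the orientation requirement, 5 with Cy3 alone and 2 with at least 6 probes. Regions carried by all 8 animals, 1 as reported, were 0 with the other 7 animals as reference, 2 without the orientation requirement, 11 and 5 with Cy5 or Cy3 alone, and 2 without progeny 6.

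More calls in progeny than in parents was kept in 16 settings (1 to 31.2) and turned to -0.83 with calls of at least 6 probes (exact permutation p = 0.571). The reported counts are mostly short calls that could not be told from chance runs, so this direction says little about copy number. Sharing of regions was kept in 17 settings (2 to 37 regions). Windows differing between progeny and parents stayed at 0 in 17 settings, where limma's unadjusted p lay under 0.05 in 2416 windows with the scan day as a block. Windows differing from the reference, 7 as reported, were 0 with the running median removed, 0 with a minimum of 0.25, 0 with windows of 5 probes (23 at an unadjusted p under 0.05), 4 with windows of 20 probes, and 0 to 7 when each animal was left out in turn. A group left with 1 parent was assumed to vary like the progeny. Group means dilute a change in 1 animal, so the absence of windows for progeny against parents does not speak for such changes.

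In the chromosome 4 gain (from 101110482), the median of the other 7 animals as reference gave -0.0190 in the female parent and -0.0358, -0.0478, -0.0284, -0.0504, -0.0257 and -0.0342 in progeny 1 to 6, since that reference carries the gain itself. With normexp signals progeny 2 turned to 0.0432 at 111324029 on chromosome 7. Of 62 region values, 13 more moved with normexp, 7 more with the other 7 animals as reference and 8 with the running median removed. No paired analysis was possible because replicate numbers only count animals within a group and pair no progeny with a parent. The animals form 1 family, and neither the permutation test nor limma allowed for their kinship. At least 98.7% of spots of an array were well above background, yet leaving out the dim probes cut the calls from 262 to 124, a filter that a loss itself can trigger. Of 16 X and Y medians, 9 moved with normexp.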

Other observations

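All tests of explanations in this part were chosen after the values were seen.

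Beyond the regions named so far, several short losses of the female parent were shared with progeny 5 or 6. On chromosome 9 (35857910 to 35868792, 5 probes) the female parent, progeny 5 and progeny 6 had -0.49, -0.55 and -0.74, and the probe at 35857910 to 35857969 read -2.49, -2.60 and -2.58 in them. On chromosome 10 (102877834 to 102881213) these animals had -0.58, -0.53 and -0.54, and on chromosome 5 (7070165 to 7075132) -0.59, -0.50 and -0.61. A gain of 4 probes on chromosome 13 (95707465 to 95714294) was carried by 7 of the 8 animals, with 0.48 in the male parent, 0.36 in the female parent, 0.30 to 0.57 in progeny 1 to 5, and 0.25 in progeny 6, where 1 orientation fell short of the minimum. Only 1 of its 4 probes was at 0.25 or above in all carriers, and without that probe, at 2.34, progeny 1 averaged -0.01.

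The losses shared by the female parent, progeny 5 and progeny 6 coincide with the animals that read low on Y. The gain on chromosome 8 from 102132083 read highest in the same animals, at 0.29, 0.24 and 0.18, and is not part of the tests below. Autosomal losses inherited from the female parent are argued against at 9 of the 11 probes: the female parent lay below the level of 1 copy, -0.86, where each progeny should lie at that level or lower, yet the lowest of progeny 1 to 4 was -0.16. At the other 2 probes, with a lowest value of -0.41, the limits were not met with normexp signals and inheritance stays open. Chance runs of probes, with noise independent between animals, are argued against as well. Progeny 5 and 6 both carried 3 of the 29 losses called in the female parent alone, against 3 of 10000 random 3-probe runs. With 1 added to both counts of random runs, the exact binomial p was 2.3e-07 (one-sided). The random runs, unlike the 29 losses, were not picked for low values in any animal. Probe or dye effects shared between arrays could therefore raise the count, and this p does not exclude them. Probe sequence shared with the Y chromosome stays open: of 22 regions of the female parent and some progeny, but not the male parent, 11 were losses in both progeny 5 and 6 and 9 in 1 of them, a count that largely restates the pattern, and probe sequences were not used here.

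The gain on chromosome 4 from 101110482 had 1 level in the male parent and another in the other 7 animals. A reference mouse with fewer copies than 8 equal animals is argued against, since the male parent lay 0.40 ± 0.02 above the mean of the others. Whether the levels are 4 copies in the male parent and 3 in the other 7 animals against 2 in the reference stays open. On the scale of the X probes all 8 animals were nearest to these numbers, with a mean of 0.53 in the other 7, but with normexp signals and their scale only 1 of the other 7 was nearest to 3 copies. A random draw from unlike chromosomes of the female parent rests on the same copy numbers, which stay open. On the scale of the X probes 6 of 6 progeny were nearest to 3 copies, the most uneven split possible (exact binomial p = 0.031, two-sided). That p lies under 0.05. The limit set for this test, after the values were seen, was stricter, so no conclusion is drawn.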
